A study of Homo sapiens with 4 samples.

How the data were processed

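Total RNA of human cancer-associated fibroblasts was profiled in 4 samples, 2 with a control hairpin construct and 2 with a hairpin against NNMT, per the labels. The constructs were delivered in a vector with a U6 promoter and a green marker, per the labels, and a single construct against NNMT was used. Biotinylated cRNA was hybridised to Illumina BeadChips, and GenomeStudio is named in the submitters' processing notes. Its version and its background settings are not given in the sources used here.

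Deposited probe intensities came in 3 forms. The deposited non-normalized intensity is positive on every array and the arrays differ in median. The authors' normalized intensity, from the values, is background-subtracted (25.4% of values lie below 0 on each array) and quantile-normalized, on a linear scale. The value table of the series holds the same values as the authors' normalized table in all 47226 rows. A detection p-value per probe and array is deposited with the intensities, per the file headers.

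Columns were assigned to samples by their names, and 0 columns of per-sample values were left unmatched. Probe identifiers were joined to array addresses by an exact match of the 4 normalized values, which paired 47224 of 47226 rows uniquely, whereas the best other column order matched 373 rows. The platform's annotation gave 1 gene for 30111 probes, several for 8 and none for 17107, and symbols of 30072 were updated through the gene identifier. A probe without a single gene stayed in the tests unnamed. No genome build is named in the sources used here, so no coordinates are given. XIST, TSIX and Y-linked genes (144 probes) were left out because the cells come from people.

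The non-normalized intensity was background-corrected with limma's neqc (limma 3.58.1, R 4.3.3), which used the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on at least 2 of 4 arrays were kept, and each gene was represented by its probe with the highest mean. This left 16281 features, 11694 of them named genes and 4587 unnamed probes. Of the 109 genes chosen by the naming rule, 41 had several detected probes, and in 2 of them (CALB2 and LEPR) a probe went the other way. Limma's lmFit and eBayes compared shNNMT with shControl, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The median fitted SE of a log2 fold change was 0.114, the residual degrees of freedom were 2 and the prior degrees of freedom 5.97. The number of arrays limits the precision. Where a probe was not detected on either array of a group, the fold is a bound: the brighter group's mean against the mean, per array of the dimmer group, of the higher of the lowest detected signal and the probe's own.

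Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. When the correlation is estimated, camera's p-values rest on the 2 residual degrees of freedom of the fit. That test therefore has little power with 4 arrays, and a list not past it may still be shifted. The 33 lists were pathways (contractile and myofibroblast, fibroblast markers, collagens, matrix glycoproteins, matrix enzymes, TGF-beta, YAP/TAZ, cytokines, NF-kappaB, interferon, MHC class I, growth factors, insulin-like growth factor binding proteins, integrins, methionine cycle, NAD, methylation enzymes, cancer-testis and imprinted, cell cycle, p53, cholesterol, unfolded protein response, hypoxia, oxidative phosphorylation, NRF2), technical lists (ribosomal proteins, immediate early genes) and markers of other cell types (epithelial, mesothelial, endothelial, leukocyte, pericyte, adipocyte). Lists with under 5 tested members were described only. Lists, tests, alternatives and the naming rule were fixed before the data were examined, except where a later passage says that a choice was made after the values were seen. The rule named NNMT, then the 12 largest rises and 12 largest falls among named genes past the threshold whose groups did not overlap, then per list up to 4 members past the threshold with the largest change, or else the 2 with the smallest p. It left out placeholder symbols and immunoglobulin or T cell receptor segments.

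The fit was tested on simulated data over 16281 features, at the real genes' mean levels. Variances were drawn from the fitted prior and genes were independent, so the data followed the fit's own model. The rates below therefore describe that model rather than these arrays. Far fewer features were changed in the simulation (138 of them called) than the 1372 called on the arrays. An adjusted p of 0.05 thus needed a smaller unadjusted p in the simulation. The share recovered, above all at 1.5-fold, can be lower there than on the arrays. For the comparison of shNNMT with shControl, it recovered 22.4% of 67 features changed 1.5-fold, 86.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 4.17% of its calls were features left unchanged. In 20 simulated draws with 1 list raised 1.4-fold, camera found that list in 20, and called 2 of 620 unchanged lists. Since the simulated genes were independent, this cannot show how often camera wrongly calls lists whose genes vary together.

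Alternatives were other background corrections (normexp with an offset of 50, or none with a floor of 16), median scaling or no normalization between arrays, the authors' normalized table with a floor of 16, other detection filters, all probes or their mean, a trended robust prior, the replicate number as a block, each array left out, stricter thresholds and other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.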

Results

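Gene expression was measured in human cancer-associated fibroblasts, the fibroblasts found in the stroma around a tumour. The cells carried a construct for a short hairpin RNA against NNMT (shNNMT) or a control construct (shControl). NNMT is nicotinamide N-methyltransferase, an enzyme that passes the methyl group of S-adenosylmethionine to nicotinamide. RNA from 2 samples of each group was hybridised as biotin-labelled cRNA to Illumina BeadChip arrays of 47226 probes, 1 array per sample. The median non-normalized intensity was 89.2 and 94.3 on the shControl arrays and 94.1 and 91.8 on the shNNMT arrays, and 19816 to 20376 probes per array had a detection p under 0.05. Across the tested features, Pearson's r was 0.997 between the shControl arrays, 0.995 between the shNNMT arrays and 0.988 to 0.991 between arrays of different groups, although genes are not independent replicates. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

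The comparison asked which transcripts differed between fibroblasts with the NNMT hairpin and fibroblasts with the control construct. NNMT itself was lower on both shNNMT arrays, with a non-normalized intensity of 535.9 and 566.4 against 2131 and 2625.3 on the shControl arrays. Its normalized log2 intensity was 8.88 ± 0.17 (SD, n = 2) in shNNMT and 11.22 ± 0.07 (SD, n = 2) in shControl. This was a 5.06-fold lower level (log2 fold change -2.34, SE 0.12, limma adjusted p = 0.000148) on the single probe of the gene. Of 16281 features tested, 1372 differed between the groups at an adjusted p of 0.05, 656 higher and 716 lower in shNNMT. Among the 11694 features with a gene symbol, 503 genes were higher and 571 lower. The larger changes lay on the lower side, where 107 features differed by at least 2-fold, against 20 on the higher side. As lists, TGF-beta target genes, collagens, matrix glycoproteins, contractile genes and hypoxia genes were lower, and cell cycle genes, interferon-stimulated genes and MHC class I genes were higher, in camera tests with a preset correlation (adjusted p between 6.44e-21 and 0.0167, and between 0.195 and 0.451 with an estimated correlation).

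**Figure D1:**
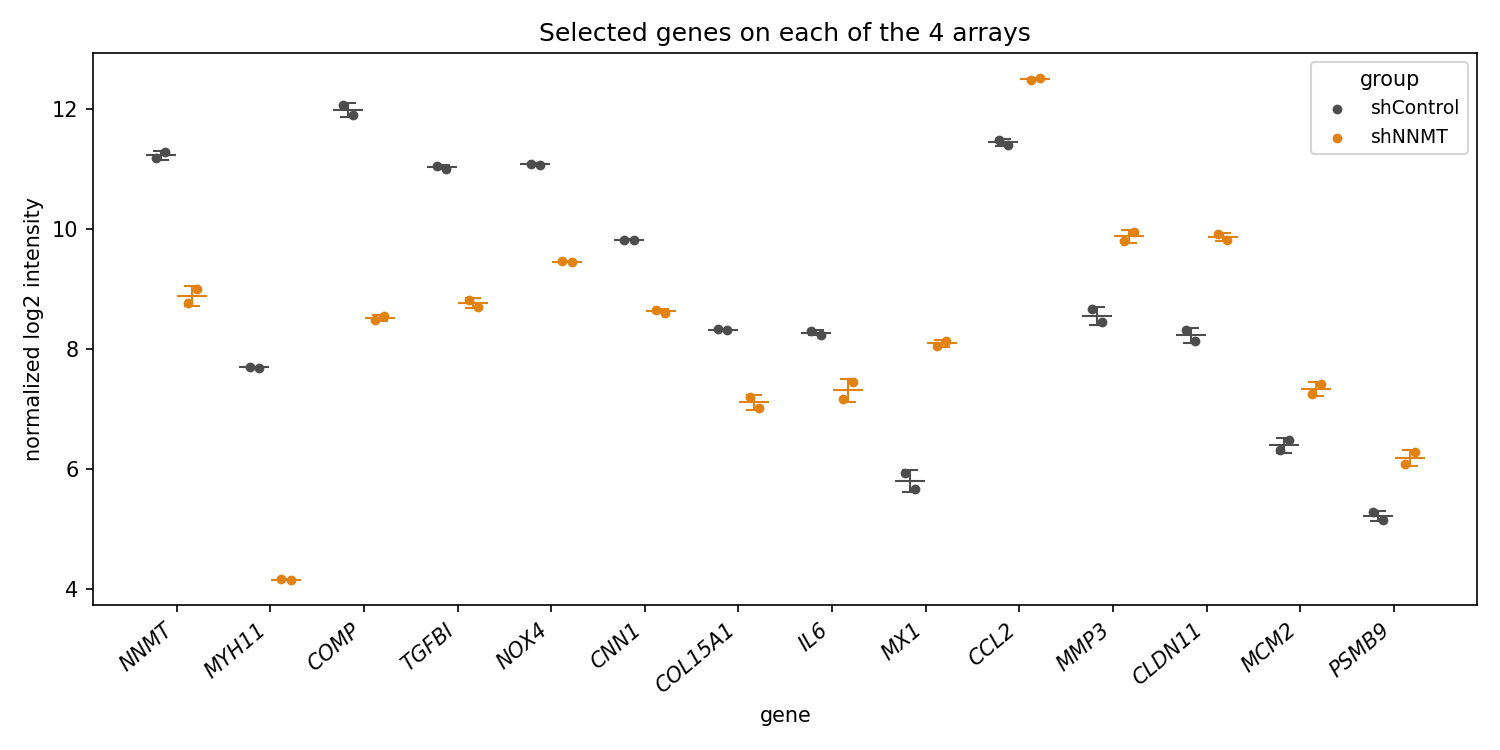
Normalized log2 intensity of 14 genes on each array. Points are the arrays of each group, horizontal bars the group means and error bars the SD (n = 2). NNMT has a mean of 11.22 on the shControl arrays and of 8.88 on the shNNMT arrays. The genes drawn were chosen among those past the test, and the groups do not overlap for any of the 1372 features past it.

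MYH11, the smooth muscle myosin heavy chain, was detected on both shControl arrays and on neither shNNMT array, and was at least 9.08-fold lower (adjusted p = 9.1e-06). COMP, a pentameric glycoprotein of cartilage and tendon matrix, fell 11.0-fold (log2 fold change -3.46, SE 0.11). ALKAL1, a ligand of the ALK and LTK receptor kinases, fell 5.80-fold, and TGFBI, a secreted matrix protein induced by TGF-beta, fell with a log2 fold change of -2.26. EFEMP1, a fibulin, fell 3.67-fold, ACTC1, the cardiac alpha-actin, 3.65-fold, RASSF2, a Ras-association domain protein, 3.62-fold, and DSP, the desmosomal protein desmoplakin, 3.29-fold. BMP6, ZPLD1 and CYP26A1 also fell, with log2 fold changes of -1.85, -1.84 and -1.82, but each was detected on only 1 of the 2 shNNMT arrays. Adjusted p-values for these falls lay between 9.1e-06 and 0.00153.

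MX1, an interferon-induced dynamin-like GTPase, rose most, by 4.90-fold (log2 fold change 2.29, SE 0.12, adjusted p = 0.000161). CLDN11, a claudin of tight junctions, rose 3.10-fold, NEFM, the medium neurofilament chain, 3.05-fold, and DIO2, the deiodinase that activates thyroxine, 2.67-fold. The proteases MMP3 and ADAMTS5, which degrade matrix proteins, rose 2.49-fold and 2.22-fold. RGCC, a regulator of the cell cycle, rose 2.45-fold, the adenosine receptor ADORA2B 2.44-fold, the orphan receptor GPRC5A 2.38-fold, the inflammatory caspase CASP1 2.33-fold and the cytokine signalling inhibitor SOCS2 2.22-fold. CYP26B1, which like CYP26A1 hydroxylates retinoic acid, rose 2.35-fold while CYP26A1 fell. Each of these 24 largest changes kept its call when any 1 array was left out.

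**Figure D2:**
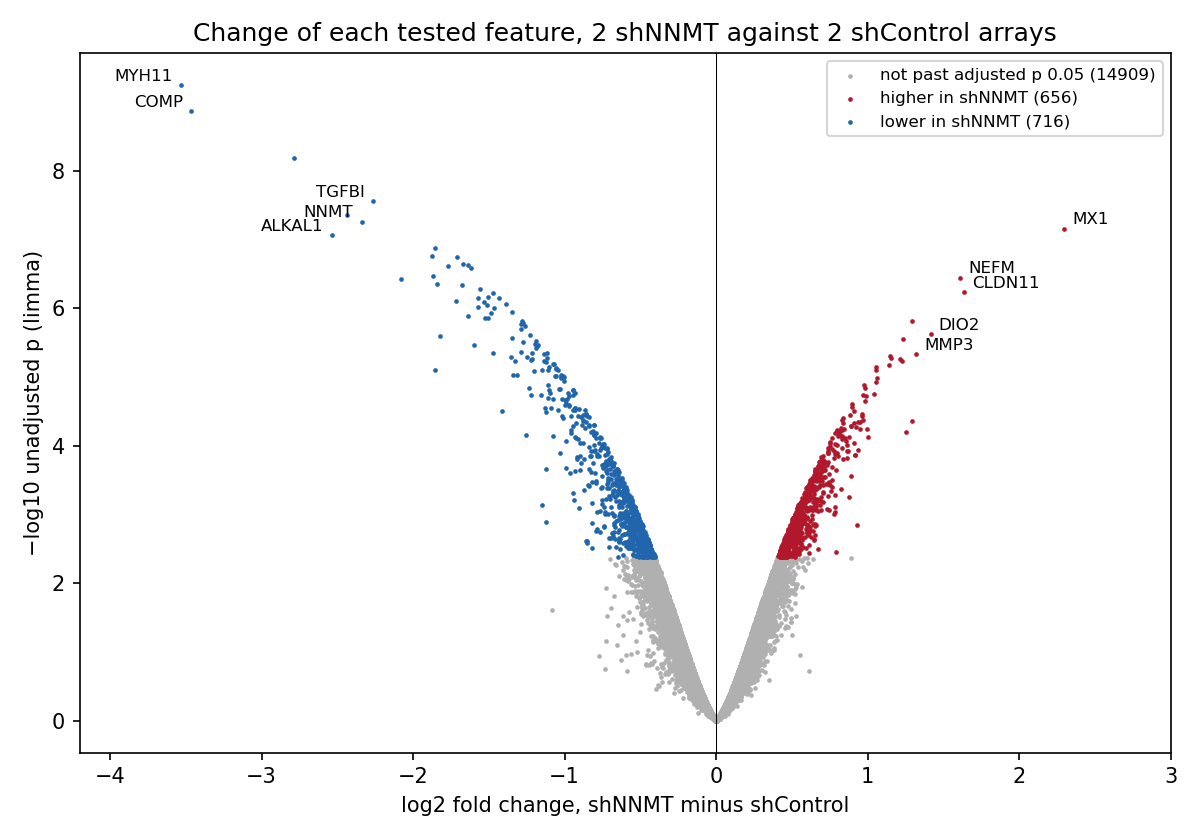
Each point is 1 of 16281 features, with the log2 fold change (shNNMT minus shControl) on the x axis and -log10 of limma's unadjusted p on the y axis. Coloured points pass an adjusted p of 0.05, 656 of them higher in shNNMT (red) and 716 lower (blue), and the farthest points lie on the lower side, at MYH11 and COMP.

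TGF-beta target genes were lower as a list, with 13 of 20 tested members lower, 0 higher and a median log2 fold change of -0.74 (16 lower when adjusted over the list alone). Limma's camera test gave the list an adjusted p of 2.86e-15 with a preset correlation and an adjusted p = 0.195 with an estimated correlation. Besides COMP and TGFBI, the oxidase NOX4 fell 3.08-fold (log2 fold change -1.62, SE 0.10) and PMEPA1, a feedback inhibitor of TGF-beta signalling, fell 2.70-fold. Without COMP, TGFBI and LTBP2, which are also on the matrix glycoprotein list, the median was -0.47.

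Collagens were lower together, with 12 of 19 tested members lower, 0 higher and a median log2 fold change of -0.55 (14 lower when adjusted over the list alone; camera adjusted p = 8.06e-12, and adjusted p = 0.195 with an estimated correlation). COL15A1 fell 2.32-fold, COL8A2 2.28-fold, COL11A1 2.04-fold and COL16A1 1.91-fold. Of the matrix glycoproteins and proteoglycans, 13 of 33 were lower and 1 higher, with a median of -0.29 (18 and 2 when adjusted over the list alone; camera adjusted p = 4.55e-09, and adjusted p = 0.195 with an estimated correlation). MFAP5, a microfibril protein, fell 1.93-fold, beside COMP, TGFBI and EFEMP1. The enzymes that crosslink or remodel matrix were not shifted as a list (7 higher and 3 lower of 31, 9 and 9 when adjusted over the list alone; camera adjusted p = 0.918), and their median of -0.14 and mean of 0.05 differed in sign, as did camera's direction (lower) and fry's (higher). Beside MMP3 and ADAMTS5, the urokinase gene PLAU rose 2.21-fold, while TIMP1, an inhibitor of metalloproteinases, fell 1.60-fold.

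The contractile and myofibroblast list was lower, with 7 of 18 tested members lower, 0 higher and a median log2 fold change of -0.33 (9 lower when adjusted over the list alone; camera adjusted p = 4.6e-06, and adjusted p = 0.195 with an estimated correlation). CNN1, the smooth muscle calponin, fell 2.28-fold (log2 fold change -1.19, SE 0.10). LPP, a focal adhesion protein, fell 1.54-fold, MYLK, the myosin light chain kinase, 1.52-fold and TNS1, a tensin, 1.51-fold. Of the pericyte and vascular smooth muscle markers, a separate list, MYH11, RGS5 and NOTCH3 fell too, and fry called that list lower (adjusted p = 0.00681) while camera did not (adjusted p = 0.163). ACTA2, the alpha-smooth muscle actin used as a myofibroblast marker, did not pass the test (log2 fold change 0.01, SE 0.11, adjusted p = 0.966), nor did TAGLN, the smooth muscle protein transgelin (-0.14, SE 0.11, adjusted p = 0.453). Both were among the brightest features (13.77 and 13.72 on the log2 scale in shControl), where the only calls were falls, so a rise could be missed. ACTA2, TAGLN and the fibroblast activation protein gene FAP (-0.11, adjusted p = 0.565) were singled out after their values were seen. The list of markers of cancer-associated fibroblasts held 3 lower and 1 higher of 16 members (4 and 2 when adjusted over the list alone) and did not pass camera (adjusted p = 0.268), while fry's directional test called it lower (adjusted p = 0.00842). On it, the collagen-binding integrin ITGA11 fell 2.45-fold and the matrix protein SPARC 1.69-fold, and the membrane protease MME rose 2.01-fold.

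Interferon-stimulated genes were higher as a list, with 15 of 34 tested members higher, 1 lower and a median log2 fold change of 0.34 (16 and 1 when adjusted over the list alone). The camera adjusted p was 1.26e-06, and the adjusted p = 0.195 with an estimated correlation. IFIT3, which takes part in the antiviral response, rose 1.91-fold, with MX1 the farthest at 4.90-fold. HERC5, the ligase for the ubiquitin-like protein ISG15, rose 1.88-fold from shControl log2 values of 4.52 and 4.60. The lowest detected values on those arrays were 4.52 and 4.50, so the fold of HERC5 starts from a signal near the detection limit. MHC class I and antigen processing genes had a median of 0.22, with 3 of 15 members higher and 0 lower (3 and 0 when adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.451 with an estimated correlation). The members past the test were the immunoproteasome subunits PSMB9, which rose 1.95-fold, and PSMB8, which rose 1.66-fold, and HLA-B, which rose 1.35-fold on a probe that close HLA copies could share.

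Cytokine and chemokine genes were not shifted as a list (5 higher and 1 lower of 14, 7 and 3 when adjusted over the list alone; camera adjusted p = 0.268). The monocyte chemoattractant CCL2 rose 2.08-fold, from a log2 intensity of 11.44 ± 0.05 to 12.49 ± 0.02 (SD, n = 2). CCL7, detected on 1 of the 2 shControl arrays, had a log2 fold change of 1.04. The cytokine IL6 fell 1.94-fold. NF-kappaB target genes held 1 higher and 2 lower of 17 (3 and 2 when adjusted over the list alone; camera adjusted p = 0.484). NFKBIZ, a nuclear regulator of NF-kappaB, fell 1.88-fold. The growth factor and angiogenic factor list held 1 higher and 4 lower of 26 (2 and 6 when adjusted over the list alone; camera adjusted p = 0.288). ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell 2.15-fold and the ERBB ligand gene NRG1 fell 1.96-fold. IGFBP3, which binds insulin-like growth factors, fell 2.55-fold, 1 of 2 lower members of the 6 on its list (0 higher, and 2 lower when adjusted over the list alone; camera adjusted p = 0.0619).

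Cell cycle genes were higher as a list, with 31 of 39 tested members higher, 0 lower and a median log2 fold change of 0.57 (34 higher when adjusted over the list alone). The camera adjusted p was 6.44e-21, and the adjusted p = 0.195 with an estimated correlation. MCM2, a subunit of the replicative helicase, rose 1.91-fold (log2 fold change 0.94, SE 0.12), CENPA, the centromeric histone variant, 1.79-fold, CCNB2, a mitotic cyclin, 1.78-fold and GINS2, a replication factor, 1.73-fold. The p53 and senescence list was not shifted (0 higher and 3 lower of 20, 2 and 3 when adjusted over the list alone; camera adjusted p = 0.729), and its median of 0.02 differed in sign from its mean of -0.04 and from camera's direction. Its lower members were TP53I3, a p53-induced oxidoreductase (2.17-fold), and the inhibitors of cyclin-dependent kinases CDKN2B (1.64-fold) and CDKN1A (1.58-fold).

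Hypoxia and glycolysis genes had a median of -0.21, with 4 of 27 lower and 1 higher (5 and 1 when adjusted over the list alone; camera adjusted p = 0.00316, and adjusted p = 0.449 with an estimated correlation). The call was lost with median scaling (adjusted p = 0.0519) and without between-array normalization (adjusted p = 0.0593). ANKRD37, a hypoxia-induced gene, fell 2.17-fold and ADM, the vasodilator adrenomedullin, rose 1.44-fold. Enzymes of NAD metabolism, the substrate pathway of NNMT, held 5 higher and 0 lower of 20 (6 and 0 when adjusted over the list alone) and were not shifted as a list (camera adjusted p = 0.0917). NAMPT, the salvage enzyme that recycles nicotinamide, and QPRT, of the synthesis of NAD from tryptophan, each rose 1.47-fold. The methionine cycle and one-carbon list held 3 higher and 0 lower of 24 (4 and 0 when adjusted over the list alone; camera adjusted p = 0.0619), among them SHMT1, the cytosolic serine hydroxymethyltransferase, at 1.72-fold. Of the enzymes that write or erase histone and DNA methylation, 2 of 33 were higher and 2 lower (3 and 2 when adjusted over the list alone; camera adjusted p = 0.918). UHRF1, a cofactor of maintenance DNA methylation, rose 1.56-fold and KDM5B, a histone demethylase, fell 1.51-fold.

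Further pathway lists did not pass camera, although fry's directional test, which does not compare a list with other genes, called YAP/TAZ targets lower (adjusted p = 0.0128) and oxidative phosphorylation genes higher (adjusted p = 0.0275). YAP/TAZ targets held 2 higher and 4 lower of 21 (2 and 4 when adjusted over the list alone; camera adjusted p = 0.172), among them F3, the coagulation tissue factor, which rose 1.59-fold, and IGFBP3. Integrins and adhesion receptors held 1 higher and 4 lower of 24 (2 and 7 when adjusted over the list alone; camera adjusted p = 0.062), with ITGA11 the farthest. Of cholesterol synthesis genes, 1 of 26 was higher and 0 lower (1 and 0 when adjusted over the list alone; camera adjusted p = 0.33), namely SREBF1, a regulator of lipid synthesis, at 1.78-fold. The unfolded protein response and ATF4 list held 1 higher and 0 lower of 28 (1 and 4 when adjusted over the list alone; camera adjusted p = 0.438), and the higher member was the cystine transporter SLC7A11 at 1.48-fold. NRF2 and glutathione genes held 2 higher and 1 lower of 19 (2 and 2 when adjusted over the list alone; camera adjusted p = 0.687), and the lower member was GCLM, a subunit of the enzyme that starts glutathione synthesis, at 1.45-fold. Cancer-testis and imprinted genes held 1 higher and 1 lower of 10 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.918), PEG10 at 1.63-fold and MEG3 at 1.62-fold. Oxidative phosphorylation genes held 0 higher and 0 lower of 30 (0 and 0 when adjusted over the list alone; camera adjusted p = 0.0917). With 0 oxidative phosphorylation genes past limma's test, the smallest p belonged to NDUFA9 (log2 fold change 0.34, adjusted p = 0.111) and SDHA (0.35, adjusted p = 0.115).

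Markers of other cell types and the technical lists were read beside these groups. Of pericyte and vascular smooth muscle markers, 3 of 8 were lower and 1 higher (3 and 1 when adjusted over the list alone; camera adjusted p = 0.163), with a median of 0.05 but a mean of -0.64 and a lower direction in camera. Beside MYH11, RGS5, a pericyte regulator of G-protein signalling, fell with a log2 fold change of -1.68, detected on 1 of the 2 shNNMT arrays, and the receptor NOTCH3 fell 1.97-fold. Mesothelial markers held 2 lower and 0 higher of 6 (2 and 2 when adjusted over the list alone; camera adjusted p = 0.676), with a median of 0.03 but a mean of -0.22 and a lower direction in camera. The calcium-binding protein CALB2 fell 3.12-fold on its brighter probe, and its other detected probe went the other way without passing the test. Epithelial and carcinoma markers held 1 lower and 0 higher of 9 (2 and 0 when adjusted over the list alone; camera adjusted p = 0.499), the lower member being the protease inhibitor SPINT2 at 2.00-fold. Leukocyte markers held 1 higher and 0 lower of 8 (1 and 0 when adjusted over the list alone; camera adjusted p = 0.684), the higher member being CD14 at 1.46-fold, and the median of -0.10 opposed it. Adipocyte and stem cell markers held 1 higher and 1 lower of 9 (1 and 2 when adjusted over the list alone; camera adjusted p = 0.924), namely PPARG, the adipogenic nuclear receptor, at 1.60-fold and the leptin receptor LEPR. Of the 14 genes on the endothelial list only TEK (log2 fold change -0.50, adjusted p = 0.111) and ENG (0.30, adjusted p = 0.118) passed the detection filter and were tested, too few for a list test. Ribosomal protein genes held 2 higher and 0 lower of 40 (1 and 0 when adjusted over the list alone; camera adjusted p = 0.0777), and immediate early and heat shock genes 0 higher and 1 lower of 18 (1 and 1 when adjusted over the list alone; camera adjusted p = 0.718).

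**Figure D3:**
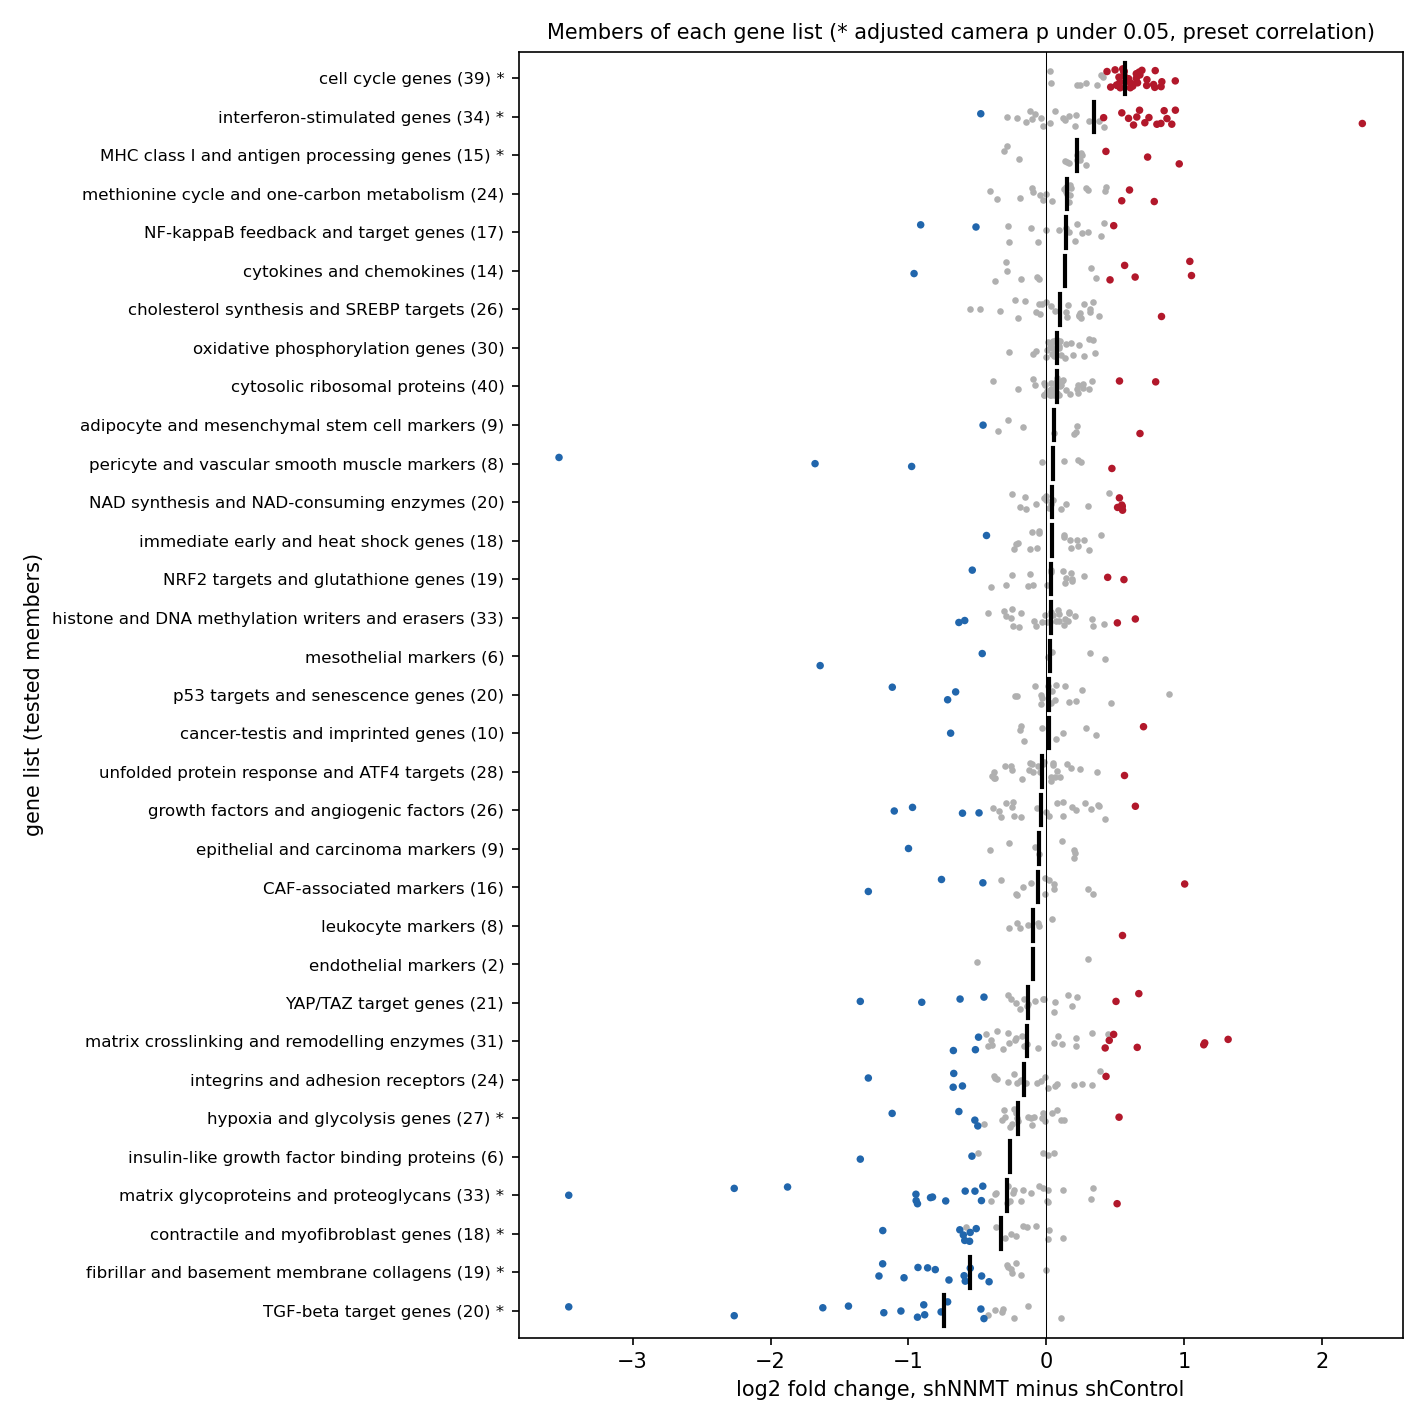
Log2 fold change (shNNMT minus shControl) of each tested member of the 33 gene lists, 1 point per gene, with coloured points past an adjusted p of 0.05 and black bars at the list medians. Asterisks mark the 8 lists past the camera test with a preset correlation, from TGF-beta target genes (median -0.74) to cell cycle genes (median 0.57), and 0 of these lists pass it with an estimated correlation.

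Of 32 lists tested, 8 passed camera with a preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. The estimated correlation was -0.0469 for the TGF-beta list, -0.026 for matrix glycoproteins and -0.0097 for contractile genes, below the preset 0.01. For the other lists of the 8 it was above 0.01. Where it was below, the higher p does not come from correlation between genes. Fry's directional test called 13, those 8 and the lists of fibroblast markers, YAP/TAZ targets, oxidative phosphorylation, insulin-like growth factor binding proteins (adjusted p = 0.037) and pericyte markers (adjusted p = 0.00681). Fry's mixed test, for change in either direction, called 32 of 32, so it set no list apart. The count of 1372 features fell to 354 without shControl replicate 1, 492 without shControl replicate 2 and 518 without shNNMT replicate 2, and to 133 on the authors' normalized table, where NNMT kept its log2 fold change of -2.34 with an adjusted p of 0.0584, and 48 of the 105 genes named by rule and past the test lost their call without at least 1 of the arrays. The authors' normalized table was used with a floor of 16, which lies above its median intensity of 4.5. With 2 samples against 2, an exact two-sided permutation test of a single gene cannot give a p under 0.333. By chance, groups fail to overlap in 33.3% of genes. Here the groups did not overlap in 9145 of 16281 features.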

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

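The interferon list without MX1 and the TGF-beta list without COMP, TGFBI and LTBP2 were tests chosen after the data were seen (medians 0.31 and -0.47, both still past camera with the preset correlation, while both full lists had an adjusted p = 0.195 with an estimated correlation); the other settings were fixed before. NNMT kept its direction in every setting run, at -2.18 to -2.46 on the log2 scale, and its call in all but the authors' normalized table and the identical series values (-2.34, adjusted p = 0.0584, against a range of 6.32e-35 to 0.0584 over all settings), where the fit had 0.472 prior degrees of freedom against 5.97. The count of changed features, 1372 (656 higher and 716 lower), became 133 (53 and 80) on those tables, 97 of them shared and all of these in the same direction, 2467 (1206 and 1261) with normexp and an offset of 50, 2385 (1204 and 1181) without background correction, 884 (415 and 469) without a detection filter, 2059 (1021 and 1038) with detection p under 0.01 on all 4 arrays, 2611 (1276 and 1335) with a trended robust prior, 678 (275 and 403) with a fold of at least 1.5 and 292 (94 and 198) at an adjusted p of 0.01. The last pair are subsets by construction; the cause of the others was not tested. Leaving out 1 array gave 354 to 1249 changed (131 to 519 higher, 223 to 730 lower), with the lone remaining sample of a group assumed to vary like the other group: 354 without shControl replicate 1, 492 without shControl replicate 2, 1249 without shNNMT replicate 1 and 518 without shNNMT replicate 2. The higher share, 47.8%, was 37.0%, 35.6%, 41.6% and 38.8% in the same order. The lists past camera, 8, became 13 with normexp and with no background correction, 15 without a detection filter, 16 with all probes, 0 with an estimated correlation (6 at an unadjusted p under 0.05), 13 with fry's directional test, and 9 to 11 with 1 array left out; the cause was not tested. With the preset correlation, the 8 lists kept their call and direction in every setting run, except hypoxia and glycolysis with median scaling and without normalization (median -0.11 in both). For named genes, the trended prior and the replicate block leave the fold change as it is. With all probes, the probe already used was followed, so these settings could not change a sign. Another probe of CALB2 (0.37, against -1.64 on the probe used) and of LEPR (0.04, against -0.46) had the opposite sign. Neither probe passed the test, and a further LEPR probe (-0.18) kept the sign. None of the 108 named genes other than NNMT changed sign in any setting run, but 85 lost their call on the authors' table, and 46, 36, 15 and 34 lost it without the 4 arrays in the order above, among them F3, GCLM, MEG3, PEG10, SLC7A11, LPP, MYLK, TNS1, TIMP1, GINS2, PSMB8, HLA-B, CDKN1A, CDKN2B, ADM, NAMPT, QPRT, UHRF1, KDM5B, CD14, PPARG and LEPR. The replicate numbers do not pair the samples on the labels, and the correlation of the replicate differences of both groups was -0.0159; with the replicate as a block 1636 features (768 and 868) and 9 lists passed. A slide block was not run, since no slide is named in the files. The other 2 splits of the 4 samples gave 0 limma calls each (168 and 170 at an unadjusted p under 0.05) against 1372, but with 3 splits no share under 0.05 is possible. Each of those splits puts 1 array of either group on each side, so the group difference enters the residual spread. Their 168 and 170 lie below the 814 expected by chance at that p, so they do not measure false calls. Signal over background limits MYH11 to a bound. At the bright end 11 other features were as bright as TAGLN or brighter, and 2 of them passed the test, both lower. Of the next 200 features by shControl level 11 passed, all lower. A limit on rises at the bright end was not tested.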

Other observations

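The family scan, the interferon list without MX1 and the use of each test below to weigh an explanation were chosen after the results were seen; the setting without between-array normalization and the gene lists were fixed before. Genes that share the letters of their symbol were scanned for an excess of calls among named genes (302 families with at least 6 tested members, 604 one-sided Fisher's exact tests, Benjamini-Hochberg adjusted). Outside the collagens, 4 families passed. Fisher's test counts genes as independent draws, which genes that change together are not. Cell division cycle associated genes (CDCA) were higher in 6 of 7 tested members, with log2 fold changes of 0.45 to 0.91 (adjusted p = 1.25e-05). Of the MCM genes, 5 of 9 were higher (MCM2, MCM4, MCM5, MCM6 and MCM7, 0.50 to 0.94, adjusted p = 0.00238), and of the IFI genes, 4 of 9 (IFI6, IFI27, IFI35 and IFI44, 0.71 to 0.88, adjusted p = 0.0433). The called MCM genes are all on the cell cycle list, and the called IFI genes other than IFI35 are on the interferon list. These families therefore largely repeat the results of those lists. Serine proteases of the PRSS family were lower in 5 of 7 members (PRSS2, PRSS3, PRSS12, PRSS23 and PRSS35, -0.77 to -0.47, adjusted p = 0.00106), of which PRSS2 and PRSS3 are close copies whose probes could cross-hybridise. The called members of each family kept their direction with median scaling, without normalization and on the authors' normalized table.

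Of the cell cycle genes, 31 of 39 tested members were higher in shNNMT, with a median log2 fold change of 0.57; as a list they passed camera with the preset correlation but not with an estimated correlation (adjusted p = 0.195). Between-array normalization does not account for it, since the median was 0.64 without that step. A lower cell density in the shNNMT dishes could also raise them, and the labels only call the dishes confluent. The YAP/TAZ target genes, which would be higher in sparse cells, had a median of -0.13, were lower in fry's directional test (adjusted p = 0.0128) but not past camera (adjusted p = 0.172), and share CCN2 with the TGF-beta list, so this stays open. A response to NNMT loss remains open as well and was not tested apart from the hairpin.

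Interferon-stimulated genes rose in shNNMT, with 15 of 34 tested members higher. MX1 alone does not carry the shift, since without it the list kept an adjusted camera p of 7.74e-06 with the preset correlation; the full list had an adjusted p = 0.195 with an estimated correlation. A candidate explanation is a response to this hairpin, or to a difference in its delivery, rather than to the loss of NNMT. Delivery of a construct as such was shared by both groups. The samples hold 1 construct against NNMT, so the construct and the loss of NNMT cannot be told apart here.

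MYH11, RGS5 and NOTCH3 fell in shNNMT, beside a lower contractile list (7 of 18 tested members lower, CNN1 with a log2 fold change of -1.19; camera adjusted p = 4.6e-06 with the preset correlation and 0.195 with an estimated correlation). A loss of pericytes or vascular smooth muscle cells from the cultures could give the fall of these markers and could add to that of the contractile list. Of 4 tested markers dimmer than MYH11 in shControl, 3 did not fall past the test, namely ABCC9 (log2 fold change 0.25) and KCNJ8 (0.23), which were not past it, and ANPEP, which rose by 0.48. The call of ANPEP was not kept without each array in turn. Fibroblasts can also express such markers, and abundant smooth muscle transcripts such as ACTA2 (13.77 on the log2 scale in shControl) have too high a level in fibroblasts to show the loss of a few cells, so this stays open. A response of the fibroblasts to NNMT loss is likewise open and untested.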
